A study of Mus musculus with 10 samples.

How the data were processed

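Single cells of the tibialis anterior of C57Bl/6 mice, uninjured or 2, 5 or 7 days after notexin, were profiled by droplet sequencing of the 3′ ends of transcripts (10x Chromium, version 2 chemistry except version 3 in day 0 C). Per the labels, muscle was digested with collagenase D and dispase II and red cells were lysed. The labels give day, replicate letter, age and sex of each of 10 libraries. They do not say whether each library comes from its own animal.

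The authors deposited raw UMI counts per gene and cell, which were used as they are. Per the submitters' notes they were made on genome build mm10 with Cell Ranger 2, and Seurat 2.3.4 and R 3.6.2 were also used. Cell filters and doublet handling are not given in the sources used here. The deposited cell table gives total UMIs and genes as counts and the mitochondrial share as a fraction, though its name says percent. Its other columns are text, the library and the authors' cell annotation. Cell totals equalled the listed UMIs in 55.9% of cells and fell short by at most 62 in the rest. The deposited normalized values were not used, since the counts they came from were at hand. The lowest total per cell ran from 1051 to 4844 UMIs between libraries.

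Annotated types were joined into 9 classes by their names. The macrophage class joins monocytes, macrophages and platelets, pro-inflammatory and anti-inflammatory macrophages, and resident macrophages and antigen-presenting cells. The lymphoid class joins B, T and natural killer cells. The other 7 are 1 annotation each. The annotation names platelets within the macrophage class and gives no neutrophil type of its own. For each library and class with at least 20 cells, UMIs were summed over cells. Summed cells numbered 156, 1641 and 786 in MuSCs at days 0, 5 and 7. They numbered 2425, 583, 2591 and 3161 in FAPs, 2678, 317, 549 and 1353 in endothelial cells, and 164, 4624, 8833 and 1096 in the macrophage class, at days 0, 2, 5 and 7.

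Differences between days were tested per class with edgeR 4.0.16 (R 4.3.3, limma 3.58.1): trimmed-mean scaling, genes kept by filterByExpr by day, and 1 quasi-likelihood fit with robust spread over all days. P-values are two-sided and were adjusted by Benjamini-Hochberg, with a threshold of 0.05. CPM are means over libraries with the SD, and the standard error of a log2 change is its size over the root of F. Against a day without counts the fold is a lower bound set against 3 counts over that day. With 1 to 3 counts it is the ratio of pooled rates with a 95% counting interval. Intervals and floors cover counting error only. The fit was tested on simulated data with 2-fold and 4-fold changes at the depth of each comparison.

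The named genes were chosen by a rule. From each list that fits the class, up to 4 members past the threshold with the largest log2 change were named, and Pax7, Myod1, Myog and the syndecans in MuSCs at any p. Then came the 5 largest rises and 5 largest falls with a mean log2 CPM of at least 5, no overlap between the libraries of the days, and a level of at least 10% of the class with the most. Predicted genes, ribosomal, mitochondrial and sex-linked genes were not named under the last part. Of the genes that the rule picks in macrophages at day 5 against 2, 2 are not reported here, nor is 1 call that turned round under a setting. The rule's last part admits only genes whose libraries lie apart, so counts of named genes apart are partly fixed. Lying apart occurs by chance for 10% of genes with 3 against 3 libraries and 20% with 3 against 2.

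A set of 28 lists was tested with camera (preset correlation 0.01, repeated with an estimated correlation) and fry. They cover quiescence, myogenic commitment, embryonic sarcomere, mature fibre transcripts, syndecans, cell cycle, interferon response, inflammatory cytokines, fibrillar matrix, basement membrane, resting FAPs, tip cells, capillary and adhesion genes of endothelium, and inflammatory and repair macrophages. They also cover antigen presentation, glycolysis, oxidative phosphorylation, cholesterol synthesis, early genes of dissociation, and erythroid, neutrophil, macrophage, endothelial, FAP, T cell and platelet markers. Mymk, Mymx and Trbc2 are not among the genes in the deposited counts. Several lists overlap with what a class itself expresses. The focus on MuSCs, the syndecans and the share test of myogenic and syndecan genes drew on recall of the published study, not on the labels, so these choices were not made blind to its topics.

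Class shares, and the shares of MuSCs with a UMI after thinning each cell to 1000 UMIs, were tested by exact permutation of the day labels (F on arcsine square roots, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Figures were drawn with matplotlib 3.10.9. Coordinates are from the GENCODE annotation of GRCm38.

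Alternatives were relative log scaling, DESeq2 1.42.0, no filter, at least 50 cells, only the libraries of the days compared, the labelled sex or the replicate letter as a term, and each library of the days compared left out. For shares they were log2 scale, edgeR on cell counts, 2000 UMIs or no thinning, and nonhematopoietic cells only. Chosen after the data were seen were cells led by their own markers, leaving out genes under 10% of another class's level, leaving out libraries whose sex transcripts go against the labels, and a common depth floor for shares. MuSCs at day 2 could not be compared, for lack of annotated cells. Day 0 libraries serve in every comparison with day 0, so counts of shared genes between comparisons were not made.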

Results

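The series holds 10 libraries of single cells from the tibialis anterior, a muscle of the lower leg, of C57Bl/6 mice. The muscle was uninjured (day 0) or had been injured 2, 5 or 7 days earlier with notexin, a snake venom toxin that destroys muscle fibres. Day 0 has 3 libraries (A, B and C), day 2 has 2 (C and D), day 5 has 3 (A, B and C) and day 7 has 2 (C and D). The submitters' purpose was charting the transcripts of the muscle's cell types over these times. The 10 libraries hold 34438 cells, 19208 genes and 309.5 M unique molecular identifiers (UMIs, counted molecules). Total UMIs ran from 7.95 to 11.4 M per library at day 0, 23.3 to 35.8 at day 2, 50.8 to 59.5 at day 5 and 21.4 to 29.0 at day 7. Cells per library ran from 1449 in day 0 C to 5429 in day 5 C, and median UMIs per cell from 2686 in day 0 B to 11807 in day 5 A. Day 0 C, the only library of version 3 chemistry, had a median mitochondrial share of 15.1% of UMIs, against 1.87% to 4.56% in the others. Animals of day 0 were 5 or 7 months old and all others 4 months, so age cannot be told apart from injury.

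Transcripts of the sex chromosomes went against the labelled sex in 3 libraries. Day 5 B, labelled female, held 0.118 counts-per-million (CPM) of Xist, the transcript of the inactive X chromosome, and a sum of 109 CPM over 4 Y-linked genes. Day 5 C and day 7 D, labelled male, held 779.8 and 936 CPM of Xist. The labels do not say whether each library came from its own animal, so p-values measure the spread between libraries, whatever its source.

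Cells annotated as monocytes or macrophages, which clear debris after injury, were 2.39% ± 0.736 of annotated cells at day 0 (SD, n = 3). They were 84.4% ± 2.95 at day 2 (n = 2), 62.4% ± 4.27 at day 5 (n = 3) and 15.7% ± 15.6 at day 7 (n = 2). The day 7 libraries stood apart, with 4.67% in C (exact Clopper-Pearson 95% interval 4.06 to 5.34) and 26.8% in D (25.3 to 28.3). Endothelial cells, which line the vessels, were 37.2% ± 13.0, 5.47% ± 1.16, 3.82% ± 1.22 and 16.7% ± 10.9 at days 0, 2, 5 and 7. Fibro-adipogenic progenitors (FAPs), the mesenchymal cells between the fibres, were 35.2% ± 12.3, 10.1% ± 1.79, 18.0% ± 3.25 and 40.7% ± 6.77. These shares depend on what they are taken over. Among nonhematopoietic cells, endothelial cells were 38.3% ± 13.4, 35.0% ± 0.821, 11.3% ± 3.94 and 19.4% ± 9.26, and FAPs were 36.3% ± 12.8, 65.0% ± 0.821, 52.2% ± 3.80 and 49.7% ± 1.97, with no other such annotation at day 2. FAPs at day 2 were thus higher than at day 0 there and lower among all cells. Muscle stem cells and progenitors (MuSCs) were 2.54% ± 1.12 at day 0, 11.3% ± 2.16 at day 5 and 10.8% ± 6.14 at day 7. Mature muscle cells were 7.62% ± 1.78 at day 0, 1.24% ± 0.0613 at day 5 and 2.00% ± 0.884 at day 7. Mature muscle markers led in 18.5% to 50.8% of these cells at day 5 against 97.5% to 100% at day 0, and 144 of 176 held at least 3 myogenic UMIs against 16 of 566, so the name covers different cells on the 2 days. B, T and natural killer cells were 0.626% ± 0.572, 3.24% ± 1.64 and 2.03% ± 1.23 at days 0, 5 and 7. Smooth muscle cells, tenocytes and glial cells were annotated at days 0 and 7 only, at 7.72% ± 1.64 and 4.78% ± 3.13, 3.07% ± 1.90 and 5.35% ± 0.00662, and 3.69% ± 0.831 and 1.82% ± 1.34. The macrophage class joins different annotations on each day. Resident macrophages and antigen-presenting cells were all of it at day 0 and 9.71% ± 1.86, 5.92% ± 2.15 and 4.16% ± 2.11 of cells at days 2, 5 and 7. The pro-inflammatory annotation held 26.5% ± 11.6 at day 2, that of monocytes, macrophages and platelets 48.2% ± 6.78 at day 2 and 22.3% ± 1.15 at day 5, and the anti-inflammatory 34.2% ± 2.64 at day 5 and 11.6% ± 13.5 at day 7.

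The annotation names its types day by day, and 3 of the 9 classes were annotated on every day. These 3 differed between days by more than the spread between libraries, in an exact permutation of the day labels over 25200 assignments (exact adjusted p over 9 classes = 0.000714 for macrophages, 0.0102 for endothelial cells and 0.0223 for FAPs). The other 6 also passed (exact adjusted p from 0.000714 to 0.0227), but against shares of 0 on days whose annotation lacks them, which do not show absence from the tissue, so their test is not read here. Digestion and cell filters also shape these shares, which describe cells recovered.

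**Figure D1:**
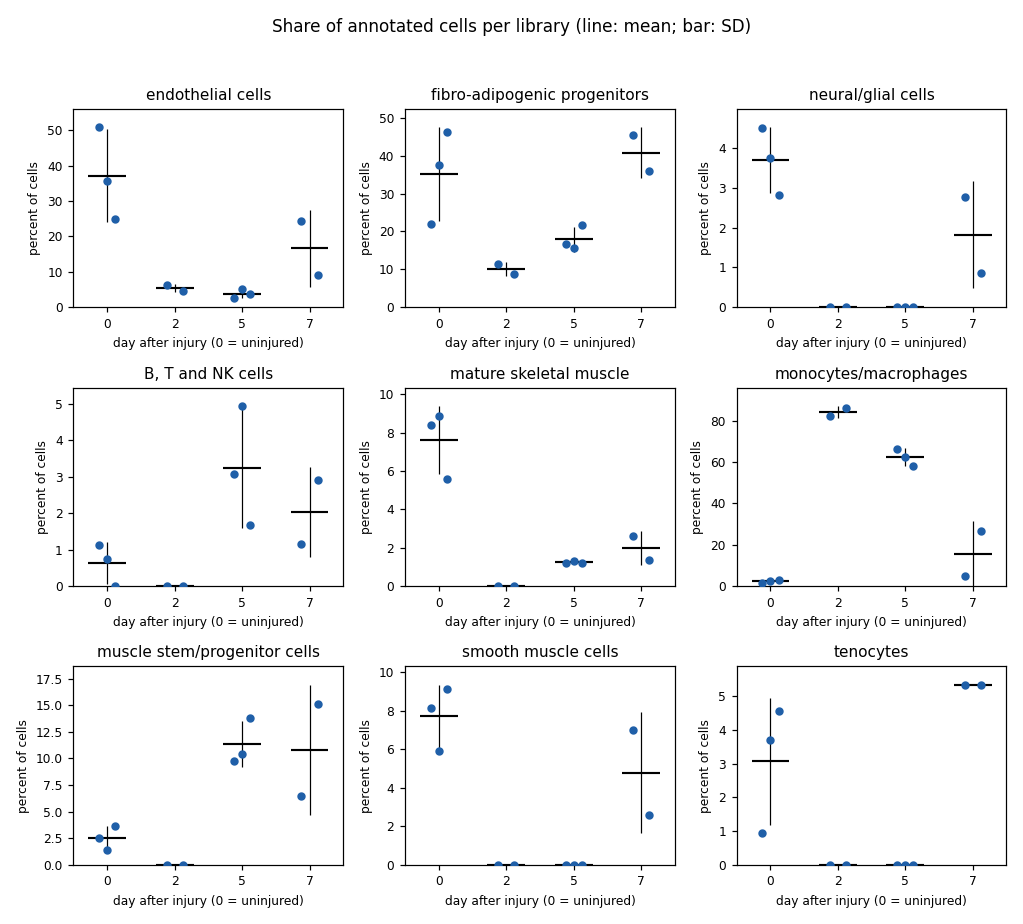
Share of annotated cells (percent, y axis) in each of 9 cell classes by day after notexin (x axis), with 1 point per library and the mean ± SD. Macrophage-class cells reach 84.4% at day 2 and the day 7 libraries lie at 4.67% and 26.8%.

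In MuSCs, the share of cells with a UMI of Pax7, the transcription factor of quiescent satellite cells (chromosome 4, 139737062 to 139833528, minus strand, GRCm38), was read in cells thinned to 1000 UMIs. It was 36.0% ± 4.67 at day 0 (n = 3), 10.3% ± 0.876 at day 5 (n = 3) and 17.5% ± 3.20 at day 7 (n = 2). Cells with a UMI of Sdc1, a heparan sulfate proteoglycan of the surface (chromosome 12, 8771323 to 8793715, plus strand), were 0%, 11.7% ± 3.88 and 3.43% ± 4.35, and those with Mki67, a marker of dividing cells, 0%, 4.25% ± 0.311 and 2.51% ± 2.03. A count of 0 in the 156 cells of day 0 allows a share of up to 1.92%. These 3 of 9 genes differed between days in an exact permutation of the day labels (560 assignments), with adjusted p of 0.0161 for Pax7 and Sdc1 and 0.0214 for Mki67. At 2000 UMIs Sdc1 alone passed (exact adjusted p = 0.0321), with 0.0707 for Pax7 and 0.0643 for Mki67. Without thinning Sdc1, Mki67, Sdc2 and Myog passed, and Pax7 had an exact adjusted p of 0.779. Shares for the proteoglycan Sdc4 (chromosome 2, 164424247 to 164443887, minus strand) were 50.4% ± 9.54, 13.6% ± 1.4 and 34.4% ± 27.9 (adjusted p = 0.138, same exact test). Those for the myogenic factor Myod1 (chromosome 7, 46376474 to 46379099, plus strand) were 29.7% ± 12.8, 12.2% ± 3.27 and 13.3% ± 2.02 (exact adjusted p = 0.138). For myogenin, Myog (chromosome 1, 134289989 to 134292548, plus strand), they were 1.99% ± 2.04, 13.2% ± 2.86 and 11.6% ± 11.3 (exact adjusted p = 0.138). Sdc2 (chromosome 15, 32920723 to 33034935, plus strand) stood at 6.45% ± 2.35, 14.0% ± 1.63 and 7.72% ± 3.31 (exact adjusted p = 0.104) and the myogenic factor Myf5 at 11.7% ± 8.67, 16.9% ± 1.38 and 18.7% ± 0.994 (exact adjusted p = 0.474). Sdc3 (chromosome 4, 130792537 to 130826319, plus strand) stood at 2.57% ± 2.87, 1.98% ± 0.215 and 1.90% ± 0.660 (exact adjusted p = 0.957), at the level of lymphoid cells on day 5 (2%). As background, day 5 lymphoid cells thinned alike held Pax7 and Sdc1 in 0.222% of 450 cells each (exact Clopper-Pearson 95% interval 0.00563 to 1.23), Mki67 in 3.78% (2.22 to 5.98) and Sdc4 in 5.56% (3.63 to 8.09), with a median of 6529 UMIs before thinning against 11312 in day 5 MuSCs. The lymphoid cells include dividing ones, so their Mki67 share is not free RNA alone. Day 5 FAPs held Sdc1 in 6.64% (5.71 to 7.67), Sdc2 in 20.5% (19.0 to 22.1) and Sdc3 in 5.98% (5.10 to 6.97), so these are not particular to MuSCs. Without any 1 of day 0 A, B or C, day 5 A or C, or day 7 C, 0 of 9 genes passed the exact permutation test, with 3 to 5 at unadjusted p under 0.05.

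No cell of day 2 carried the MuSC annotation (0 of 3654 in C and 0 of 1870 in D, which allows annotated shares of up to 0.0821% and 0.160%), so no test of MuSCs at day 2 was made.

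The comparison of MuSCs 5 days after injury with uninjured MuSCs asked how the stem cell's transcripts differ during repair. MuSC markers led in 24.5% to 52.8% of the cells so annotated per library at day 0, 80.5% to 88.5% at day 5 and 31.5% and 59.2% at day 7. Some transcripts of quiescent satellite cells fell and many of dividing cells rose, in lists whose calls were lost with an estimated correlation. Pax7 fell 4.12-fold, from 338 ± 170.0 to 83.4 ± 4.85 CPM (SD, n = 3 and 3; log2 change -2.04 ± 0.34, edgeR adjusted p = 0.00346). Chrdl2, an antagonist of bone morphogenetic proteins (BMPs), fell 162-fold, and Bmp4, one of those proteins, fell 92.8-fold, from 185 ± 64.4 to 1.92 ± 0.143 CPM. Calcr, the calcitonin receptor that holds satellite cells in quiescence, fell 15.5-fold. Spry1, an inhibitor of growth factor signalling needed for return to quiescence, fell 4.60-fold, and the surface sialomucin Cd34 fell 21.0-fold. The other large falls were in Thrsp, a regulator of lipid synthesis (282-fold), Clmn, a membrane protein that binds actin (244-fold), and Slco2a1, a prostaglandin carrier (134-fold). Birc5, an inhibitor of apoptosis that acts at the centromere, had no count at day 0 and was at least 37.9-fold higher at day 5, set against 3 counts over the day (edgeR adjusted p = 0.0106). On the same bound the mitotic kinase Cdk1 was at least 26.0-fold higher, Cdc20, which drives the exit from mitosis, at least 20.7-fold, and cyclin A2, Ccna2, at least 17.6-fold. R3hdml, a secreted protein known to favour myogenic growth, was at least 23.1-fold higher.

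Among the syndecans, the heparan sulfate proteoglycans of the cell surface, Sdc1 had no count at day 0 and was at least 30.5-fold higher at day 5, at 120.0 ± 18.6 against 0 ± 0 CPM (edgeR adjusted p = 0.00557). Sdc2 rose 3.48-fold, from 46.4 ± 19.4 to 149.5 ± 10.3 CPM (edgeR adjusted p = 0.00438), and Sdc4, a marker of quiescent satellite cells, fell 5.86-fold, from 948 ± 169 to 162 ± 15.9 CPM (edgeR adjusted p = 0.0190). Sdc3, which satellite cells also carry, had a log2 change -0.15 ± 0.36 (edgeR adjusted p = 0.784). Of the myogenic factors, Myod1, which commits cells to the muscle lineage, had a log2 change -1.43 ± 0.47 (edgeR adjusted p = 0.0525), and Myog, which drives differentiation, 0.85 ± 0.98 (edgeR adjusted p = 0.562). The adhesion molecule Cdh15, M-cadherin, rose 2.41-fold. Of the sarcomere genes of embryonic fibres, troponin T2, Tnnt2, rose 24.1-fold and the cardiac actin Actc1 rose 14.8-fold. Tnni1, slow troponin I, rose by a count ratio of 43.6 (95% counting interval 7.82 to 1725), and the embryonic light chain Myl4 by a count ratio of 15.9, interval 4.39 to 132. These 4 stood at 0.0635, 0.0230, 0.0336 and 0.0274 of their level in the class with the most that day (the top class). Of the matrix genes, the metalloproteinase Adam12, known from myoblast fusion, was at least 3.76-fold higher. Periostin, Postn, rose by a count ratio of 214 (95% counting interval 38.4 to 8455), the inhibitor of matrix proteases Timp1 by a count ratio of 139.8, interval 38.7 to 1155, and tenascin C, Tnc, by a count ratio of 66.8, interval 12 to 2639. Their levels were 0.136, 0.0704, 0.243 and 0.130 of the top class.

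Of the quiescence genes, 7 of 12 fell and 5 did not pass (10 fell adjusted over the list alone, camera adjusted p = 9.70e-07, 0.140 with an estimated correlation); the second value is marked as estimated from here on. Among cell-cycle genes, 20 of 24 rose and 4 did not pass (22 rose adjusted over the list alone, camera adjusted p = 6.59e-17, 0.195 estimated). Of the fibrillar matrix genes, 15 of 21 rose and 6 did not pass (16 rose adjusted over the list alone, camera adjusted p = 1.34e-11, 0.194 estimated). Among embryonic sarcomere genes, 5 of 10 rose, 1 fell and 4 did not pass (6 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.000746, 0.140 estimated). Of the myogenic commitment genes, 1 of 8 rose and 7 did not pass (1 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.812). Among syndecans, 2 of 4 rose, 1 fell and 1 did not pass (2 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.169). Of the genes of oxidative phosphorylation, 7 of 18 rose and 11 did not pass (11 rose adjusted over the list alone, camera adjusted p = 0.000260, 0.408 estimated). Early genes that tissue digestion induces went the other way. Of these, 16 of 16 fell (16 fell adjusted over the list alone, camera adjusted p = 1.82e-19, 0.140 estimated). Transcripts of other cells moved with these groups. Among macrophage markers, 7 of 7 rose (7 rose adjusted over the list alone, camera adjusted p = 2.38e-08, 0.191 estimated). Of the antigen-presentation genes, 5 of 6 rose and 1 did not pass (6 rose adjusted over the list alone, camera adjusted p = 8.01e-05, 0.249 estimated). Among transcripts of mature fibres, 10 of 11 fell and 1 did not pass (10 fell adjusted over the list alone, camera adjusted p = 1.01e-16, 0.140 estimated). Of the endothelial markers, 5 of 5 fell (5 fell adjusted over the list alone, camera adjusted p = 1.16e-09, 0.140 estimated). Among platelet markers, 1 of 2 rose and 1 did not pass (1 rose adjusted over the list alone, camera adjusted p = 0.0248, 0.249 estimated). Of the erythroid markers, 4 of 4 did not pass (0 passed adjusted over the list alone, camera adjusted p = 0.156).

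Of 11637 genes tested with edgeR, 2588 changed, 1416 up and 1172 down, and 25 of 26 named genes that changed had every library of day 5 apart from every library of day 0 (all but Calcr). Simulation recovered 41% of 4-fold and 1% of 2-fold changes. The count was 1149 without day 0 C and 1256, 1329 and 1199 without day 5 A, B and C. It was 836 with the labelled sex as a term, though transcripts go against that label in 3 libraries. Without the libraries whose sex transcripts go against their labels, only A is left of day 5, so no count is read.

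**Figure D2:**
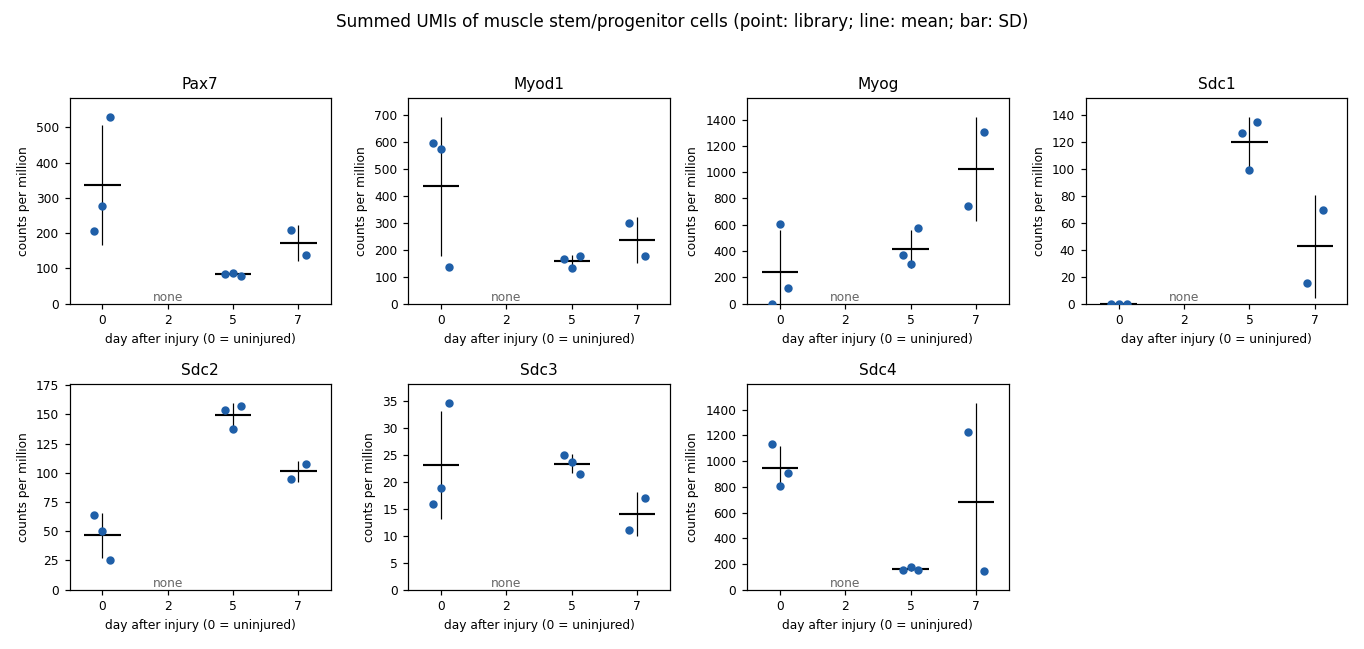
Level of Pax7, Myod1, Myog and the 4 syndecans (CPM, y axis) in MuSCs of each library by day after notexin (x axis), with the mean ± SD and error bars stopped at 0; "none" marks day 2, without annotated MuSCs. Pax7 lies at 338 ± 170 at day 0 and 83.4 ± 4.85 at day 5.

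In MuSCs 7 days after injury, against uninjured ones, some sarcomere genes of embryonic fibres rose. The cardiac actin Actc1 rose 92.4-fold, from 8.05 ± 9.72 to 506 ± 75.7 CPM (SD, n = 3 and 2; log2 change 6.53 ± 0.74, edgeR adjusted p = 0.00595), and troponin T2, Tnnt2, rose 29.1-fold. Slow troponin I, Tnni1, rose by a count ratio of 103 (95% counting interval 18.5 to 4089), and the light chain Myl4 by a count ratio of 48.5, interval 13.4 to 401. Their levels were 0.222, 1.00, 0.163 and 0.126 of the top class. Sox11, a transcription factor of progenitors in development, rose by a count ratio of 41.7 (95% counting interval 7.44 to 1652) (edgeR adjusted p = 0.00479). Cdc20, for exit from mitosis, was at least 7.89-fold higher (edgeR adjusted p = 0.0384). The type I collagen genes Col1a1 and Col1a2 rose 33.0-fold and 18.6-fold, at 0.0141 and 0.0282 of the top class. Ddit4, an inhibitor of growth signalling induced by stress, fell 3.15-fold, and Mllt4, the junction protein afadin, fell 4.51-fold (edgeR adjusted p = 0.0482).

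Pax7 had a log2 change -1.0 ± 0.38 (edgeR adjusted p = 0.182), Myod1 -0.86 ± 0.53 (edgeR adjusted p = 0.387) and Myog 2.14 ± 1.08 (edgeR adjusted p = 0.294). Sdc1 had no count at day 0 and lay at 42.5 ± 38.4 against 0 ± 0 CPM, at least 10.8-fold higher (edgeR adjusted p = 0.0813). Sdc2 had a log2 change 1.24 ± 0.34 (edgeR adjusted p = 0.0947), Sdc3 -0.80 ± 0.40 (edgeR adjusted p = 0.283) and Sdc4 -0.47 ± 0.66 (edgeR adjusted p = 0.734). Among embryonic sarcomere genes, 4 of 10 rose and 6 did not pass (8 rose adjusted over the list alone, camera adjusted p = 1.29e-18, 0.0347 estimated). Of the cell-cycle genes, 1 of 24 rose and 23 did not pass (21 rose adjusted over the list alone, camera adjusted p = 3.37e-18, 0.246 estimated). Among fibrillar matrix genes, 2 of 21 rose and 19 did not pass (17 rose adjusted over the list alone, camera adjusted p = 2.12e-15, 0.181 estimated). Of the quiescence genes, 12 of 12 did not pass (0 passed adjusted over the list alone, camera adjusted p = 0.00806, 0.434 estimated). Among FAP markers, 1 of 5 rose and 4 did not pass (2 rose adjusted over the list alone, camera adjusted p = 0.00105, 0.172 estimated). For macrophage markers, 7 of 7 did not pass (1 rose adjusted over the list alone, camera adjusted p = 0.0203, 0.571 estimated). For antigen presentation, 6 of 6 did not pass (3 rose adjusted over the list alone, camera adjusted p = 0.00104, 0.434 estimated). For endothelial markers, 5 of 5 did not pass (5 fell adjusted over the list alone, camera adjusted p = 3.94e-08, 0.0910 estimated). Of 11637 genes, edgeR called 24, 16 up and 8 down, with 2425 at unadjusted p under 0.05, and 10 of 10 named changed genes had the libraries of the days apart. Simulations found 33% of 4-fold and 0% of 2-fold changes, and 10.8% of their calls were unchanged genes. The count was 11 and 5 without day 0 A and B and 704 with DESeq2. Without day 7 C, without day 7 D, or without the libraries at odds with their sex labels, day 7 is 1 library, so no count is read. The share higher was 66.7% with the trimmed-mean scaling, 47.0% in DESeq2 and 48.3% with relative log scaling, which moved the changes by -0.151 log2.

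FAPs 2 days after injury, against uninjured ones, carried less of many resting FAP genes and more of chemokine and division genes. Gelsolin, Gsn, which severs actin filaments, fell 35.5-fold, from 41371 ± 16694 to 1167 ± 139.8 CPM (SD, n = 3 and 2; log2 change -5.15 ± 0.97, edgeR adjusted p = 0.00351). Pi16, a marker of stromal progenitors, fell 27.7-fold, Cd55, which shields cells from complement, fell 16.2-fold, and the apolipoprotein Apod fell 15.5-fold. Cxcl5, a chemokine that draws neutrophils, rose 559-fold, from 2.24 ± 1.79 to 1126 ± 902 CPM (edgeR adjusted p = 0.000445), and the acute-phase protein Saa3, with no count at day 0, was at least 228-fold higher. Division genes rose together: Birc5 142-fold, the mitotic trigger Cdca3 178-fold, thymidine kinase Tk1 151-fold, Ccna2 71.2-fold and Cdk1 57.6-fold. The mitotic kinase Aurkb rose by a count ratio of 131 (95% counting interval 44.4 to 637).

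Among matrix genes, Timp1 rose 88.2-fold, Adam12 rose 63.9-fold, Postn rose 17.5-fold and the collagen cross-linker Lox rose 8.08-fold. Of the basement membrane, collagen XV, Col15a1, fell 11.4-fold, laminin alpha 2, Lama2, fell 10.7-fold, nidogen, Nid1, fell 4.11-fold and the laminin chain Lamc1 fell 3.90-fold. The complement proteases C1rb and C1s2, near copies of other genes and so uncertain, fell by a count ratio of 1645 (95% counting interval 295 to 65012) and by a count ratio of 789, interval 218 to 6522. The methyltransferase Inmt fell by a count ratio of 637 (95% counting interval 217 to 3089), the lipase Ces1d fell 158-fold and hemicentin 2, Hmcn2, fell 50.5-fold. Of the interferon-induced genes, Cxcl10, a chemokine for T cells, rose 9.35-fold, the nucleic acid sensor Zbp1 rose 9.50-fold, Ifit3 rose 6.50-fold and the factor Irf7 rose 5.83-fold. The macrophage cytokine Il1b rose by a count ratio of 73.2 (95% counting interval 24.7 to 358), and the chemokines Ccl4 and Ccl3 rose 51.7-fold and 29.9-fold. These 3 stood at 0.0701, 0.0855 and 0.0742 of the top class.

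Of the cell-cycle genes, 24 of 24 rose (24 rose adjusted over the list alone, camera adjusted p = 3.59e-38, 0.0163 estimated). Among resting FAP genes, 1 of 14 rose, 10 fell and 3 did not pass (1 rose and 10 fell adjusted over the list alone, camera adjusted p = 5.73e-06, 0.227 estimated). Of the basement membrane genes, 9 of 10 fell and 1 did not pass (10 fell adjusted over the list alone, camera adjusted p = 5.73e-06, 0.227 estimated). Among fibrillar matrix genes, 5 of 21 rose, 3 fell and 13 did not pass (7 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.410). Of the cytokines, 9 of 12 rose and 3 did not pass (11 rose adjusted over the list alone, camera adjusted p = 2.71e-07, 0.227 estimated). Among interferon-induced genes, 9 of 15 rose and 6 did not pass (11 rose adjusted over the list alone, camera adjusted p = 0.00215, 0.457 estimated). Of the glycolytic genes, 7 of 12 rose, 1 fell and 4 did not pass (8 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.000636, 0.368 estimated). Markers of other cells moved beside them. Among macrophage markers, 7 of 7 rose (7 rose adjusted over the list alone, camera adjusted p = 9.66e-06, 0.227 estimated). Of the neutrophil markers, 3 of 3 rose (3 rose adjusted over the list alone, camera adjusted p = 0.0609). Among mature fibre transcripts, 11 of 11 fell (11 fell adjusted over the list alone, camera adjusted p = 2.67e-15, 0.177 estimated). Median log2 changes were -5.80 for erythroid, -3.24 for endothelial and 4.94 for platelet markers and -1.40 for early genes of digestion. Of these, 1 of 4, 3 of 5, 0 of 3 and 10 of 16 fell (3, 3, 0 and 11 adjusted over the list alone) and 0, 0, 2 and 1 rose (0, 0, 2 and 2). Of 13515 genes, edgeR called 4492, 2295 up and 2197 down, and 32 of 32 named changed genes had the libraries of the days apart. Simulated 4-fold changes were recovered at 59% and 2-fold at 7%. The count was 2344 and 1969 without day 2 C and D and 2922 without the libraries at odds with their sex labels.

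FAPs 5 days after injury, against uninjured ones, carried more transcripts of some matrix genes. Periostin, Postn, rose 415-fold, from 8.50 ± 7.77 to 3784 ± 1053 CPM (SD, n = 3 and 3; log2 change 8.70 ± 1.45, edgeR adjusted p = 0.00249). Cthrc1, a secreted protein of activated fibroblasts, rose 111-fold, Adam12 rose 118-fold and tenascin C, Tnc, rose 103-fold. Saa3, with no count at day 0, was at least 585-fold higher, haptoglobin, Hp, an acute-phase protein, rose 522-fold, and Ddah1, which relieves the block on nitric oxide synthesis, rose 246-fold. Osteopontin, Spp1, a matrix protein that macrophages also secrete, rose 468-fold, at 0.168 of the top class. Of the resting FAP genes, in a list whose call was lost with an estimated correlation, adipsin, Cfd, rose by a count ratio of 67.1 (95% counting interval 18.5 to 555), while Gsn fell 25-fold, Pi16 fell 12.8-fold and Cd55 fell 11.2-fold. Outside that list, Ces1d fell 77.3-fold and Inmt fell 30.2-fold. C1rb and C1s2, uncertain as near copies, fell 169-fold and 122-fold.

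Division genes rose, Birc5 78.5-fold, Cdk1 41.4-fold and the centromere histone Cenpa 39.6-fold, and Aurkb rose by a count ratio of 72.9 (95% counting interval 24.9 to 355). Of the interferon-induced genes, Irf7 rose 20.1-fold, Cxcl10 rose 13.4-fold, Zbp1 rose 13.1-fold and the antiviral enzyme Rsad2 rose 12.1-fold. Cxcl5 rose 10.4-fold. Il1b rose by a count ratio of 48.4 (95% counting interval 16.5 to 235), Ccl4 rose 38.4-fold and Ccl3 rose 32.1-fold, at 0.0478, 0.0442 and 0.0445 of the top class. Lama2 fell 3.18-fold, Col15a1 fell 2.04-fold and Lamc1 fell 1.97-fold.

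Of the fibrillar matrix genes, 14 of 21 rose and 7 did not pass (16 rose and 1 fell adjusted over the list alone, camera adjusted p = 2.72e-07, 0.343 estimated). Among resting FAP genes, 2 of 14 rose, 11 fell and 1 did not pass (2 rose and 11 fell adjusted over the list alone, camera adjusted p = 9.46e-06, 0.238 estimated). Of the interferon-induced genes, 12 of 15 rose and 3 did not pass (13 rose adjusted over the list alone, camera adjusted p = 2.23e-06, 0.344 estimated). Among cell-cycle genes, 22 of 24 rose and 2 did not pass (22 rose adjusted over the list alone, camera adjusted p = 1.57e-25, 0.0652 estimated). Of the genes of cholesterol synthesis, 10 of 15 fell and 5 did not pass (11 fell adjusted over the list alone, camera adjusted p = 9.34e-05, 0.402 estimated). Among cytokines, 6 of 12 rose and 6 did not pass (6 rose adjusted over the list alone, camera adjusted p = 0.00368, 0.395 estimated). Of the basement membrane genes, 3 of 10 fell and 7 did not pass (3 fell adjusted over the list alone, camera adjusted p = 0.0711). Transcripts of other cells moved beside these. Among macrophage markers, 7 of 7 rose (7 rose adjusted over the list alone, camera adjusted p = 1.27e-08, 0.238 estimated). Of the repair macrophage genes, 10 of 16 rose, 1 fell and 5 did not pass (11 rose and 1 fell adjusted over the list alone, camera adjusted p = 4.79e-07, 0.238 estimated). Among mature fibre transcripts, 11 of 11 fell (11 fell adjusted over the list alone, camera adjusted p = 2.71e-17, 0.154 estimated). Markers of tenocytes, a matrix-rich type annotated at days 0 and 7 alone, rose too, picked after their values were seen: Thbs4 (log2 change 4.16 ± 0.83, edgeR adjusted p = 0.00502), Fmod (2.14 ± 0.58) and Tnmd (1.79 ± 0.47). Of the T cell markers, 2 of 2 did not pass (0 passed adjusted over the list alone, camera adjusted p = 0.741). Of 13515 genes, edgeR called 4404, 2277 up and 2127 down, and 31 of 31 named changed genes had the libraries of the days apart. Simulation recovered 72% of 4-fold and 9% of 2-fold changes. The count was 2550 and 2511 without day 5 A and C and 1402 with the labelled sex as a term. Without the libraries at odds with their sex labels only A is left of day 5, so no count is read.

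**Figure D3:**
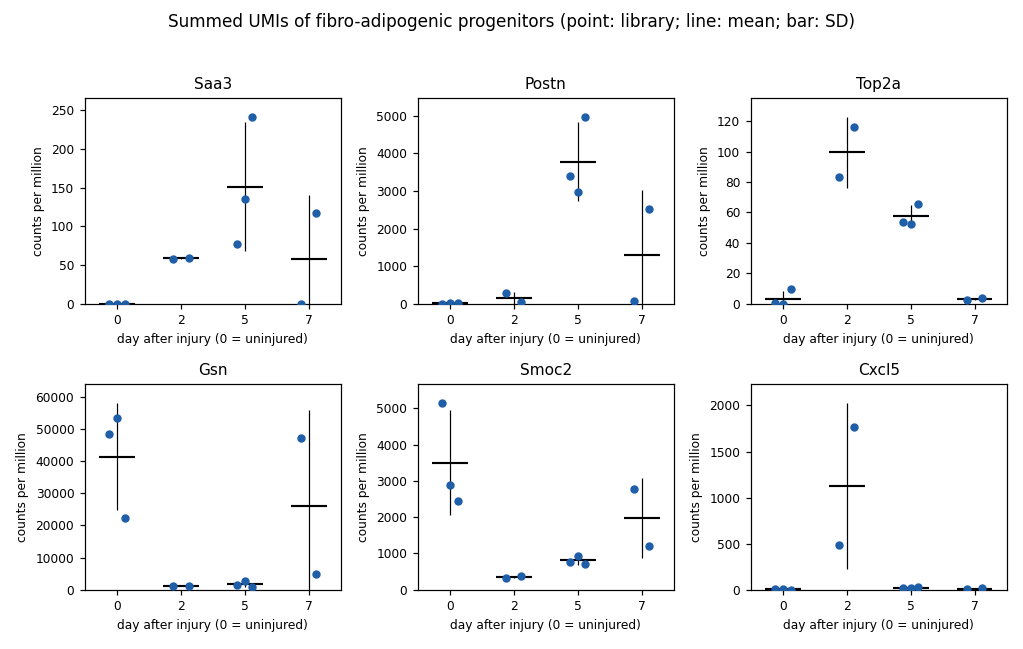
Level of Saa3, Postn, Top2a, Gsn, Smoc2 and Cxcl5 (CPM, y axis) in FAPs of each library by day after notexin (x axis), with the mean ± SD and error bars stopped at 0. Gsn falls from 41371 ± 16694 to 1655 ± 864 CPM between days 0 and 5.

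FAPs of day 7 gave few calls against day 0, over 2 unlike libraries. C and D held 47044 and 5016 CPM of Gsn and 62.8 and 2513 of Postn, so no return to rest is shown. Cxcl10 rose 15.5-fold, from 13.5 ± 6.93 to 217 ± 111 CPM (SD, n = 3 and 2; log2 change 3.96 ± 0.51, edgeR adjusted p = 0.0260). C1s2 fell 66.4-fold and C1rb fell 59.6-fold, both uncertain as near copies. Among interferon-induced genes, 1 of 15 rose and 14 did not pass (13 rose adjusted over the list alone, camera adjusted p = 1.95e-18, 0.199 estimated). Of the fibrillar matrix genes, 21 of 21 did not pass (10 rose adjusted over the list alone, camera adjusted p = 4.65e-09, 0.265 estimated). Among resting FAP genes, 14 of 14 did not pass (0 passed adjusted over the list alone, camera adjusted p = 0.0197, 0.504 estimated). Of the cell-cycle genes, 24 of 24 did not pass (0 passed adjusted over the list alone, camera adjusted p = 0.0588). Among macrophage markers, 7 of 7 did not pass (6 rose adjusted over the list alone, camera adjusted p = 2.34e-07, 0.199 estimated). Of 13515 genes, edgeR called 6, 1 up and 5 down, with 1538 at unadjusted p under 0.05. Simulations found 55% of 4-fold and 3% of 2-fold changes. The count was 25 without day 0 C and 253 with DESeq2. DESeq2 called 71.5% of its genes higher, against 16.7% here.

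Endothelial cells 2 days after injury, against uninjured ones, carried more of many chemokine transcripts and less of some of the capillary wall. Pgf, placental growth factor, rose 35.0-fold, from 6.85 ± 4.41 to 247 ± 79.3 CPM (SD, n = 3 and 2; log2 change 5.13 ± 0.55, edgeR adjusted p = 0.000877). Apelin, Apln, a peptide of sprouting tips, rose 29.0-fold, and Mcam, an adhesion molecule of endothelial and mural cells, rose 4.59-fold. Kdr, the main receptor for vascular growth factor, fell 3.98-fold, from 804 ± 337 to 202 ± 34.5 CPM. The fatty acid carrier Cd36 fell 3.47-fold, the factor Tcf15 of heart and muscle capillaries fell 4.42-fold, Rgcc fell 3.98-fold and the sialomucin Cd300lg fell 4.38-fold. Timp4, a protease inhibitor, fell 25-fold, Cyp26b1, which breaks down retinoic acid, fell 56.4-fold, the growth factor Fgf9 fell 12.7-fold and the nucleoside carrier Slc28a2 fell 11.6-fold. Klra9, of a receptor family of near copies and so uncertain, fell 82.9-fold.

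Birc5, Mki67, Ccna2 and Aurkb had no count at day 0 and were at least 169-fold, at least 94.2-fold, at least 53.8-fold and at least 28.3-fold higher. The chemokine Ccl7 rose 62.2-fold, Ccl4 rose 196-fold, Il1b rose 179.7-fold and Ccl3 rose by a count ratio of 277 (95% counting interval 75.7 to 2303). These 4 stood at 0.0728, 0.420, 0.263 and 0.478 of the top class. Macrophage transcripts rose: the protease Ctss 665-fold, the lipid receptor Trem2 a count ratio of 422, interval 116 to 3498, and Aif1 a count ratio of 279.7, interval 76.4 to 2326. They stood at 0.104, 0.113 and 0.106 of the top class. Of the matrix genes, Timp1 rose 56.9-fold, Mmp14 rose 10.6-fold, Adam12 rose by a count ratio of 30.9 (95% counting interval 4.49 to 1331) and Mmp2 fell 10.5-fold, at 0.0492, 0.562, 0.0578 and 0.0160 of the top class. Zbp1 rose 16.6-fold, Cxcl10 rose 3.15-fold and Irf7 rose 2.66-fold.

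Of the cytokines, 8 of 10 rose and 2 did not pass (8 rose adjusted over the list alone, camera adjusted p = 4.98e-12, 0.0213 estimated). Among genes of inflammatory macrophages, 8 of 13 rose and 5 did not pass (8 rose adjusted over the list alone, camera adjusted p = 2.88e-10, 0.0213 estimated). Of the capillary genes, 7 of 12 fell and 5 did not pass (8 fell adjusted over the list alone, camera adjusted p = 2.78e-05, 0.315 estimated). Among tip cell genes, 3 of 15 rose, 5 fell and 7 did not pass (3 rose and 6 fell adjusted over the list alone, camera adjusted p = 0.699, with a median log2 change of -0.55, a mean of 0.29 and a test directed up). Of the adhesion genes, 5 of 5 did not pass (0 passed adjusted over the list alone, camera adjusted p = 0.322). Among cell-cycle genes, 17 of 24 rose and 7 did not pass (21 rose adjusted over the list alone, camera adjusted p = 4.02e-12, 0.315 estimated). Of the interferon-induced genes, 3 of 15 rose and 12 did not pass (4 rose adjusted over the list alone, camera adjusted p = 0.0912). Among fibrillar matrix genes, 6 of 21 rose, 1 fell and 14 did not pass (8 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0366, 0.556 estimated). Transcripts of other cells moved beside these. Of the macrophage markers, 7 of 7 rose (7 rose adjusted over the list alone, camera adjusted p = 8.42e-12, 0.166 estimated). Among mature fibre transcripts, 10 of 11 fell and 1 did not pass (11 fell adjusted over the list alone, camera adjusted p = 3.36e-11, 0.166 estimated). For neutrophil markers, 3 of 3 rose (3 rose adjusted over the list alone, camera adjusted p = 0.00498, 0.233 estimated). Of 11234 genes, edgeR called 1996, 1130 up and 866 down, and 31 of 31 named changed genes had the libraries of the days apart. Simulated 4-fold changes were recovered at 62% and 2-fold at 8%. The count was 592 and 361 without day 2 C and D and 979 without the libraries at odds with their sex labels.

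Endothelial cells 5 days after injury, against uninjured ones, carried more of some interferon-induced and adhesion genes. Irf7 rose 9.41-fold, from 43.7 ± 9.57 to 412 ± 157 CPM (SD, n = 3 and 3; log2 change 3.23 ± 0.40, edgeR adjusted p = 0.00119). Cxcl10 rose 12.1-fold, Zbp1 rose 24.5-fold and Ifit3 rose 4.42-fold. P-selectin, Selp, which captures leukocytes, rose 7.62-fold, Vcam1 rose 2.57-fold, and E-selectin, Sele, with no count at day 0, was at least 15.5-fold higher. The cytokine Il6 rose 27.4-fold, from 7.50 ± 4.85 to 210.1 ± 54.9 CPM. Of the tip cell genes, Pgf rose 9.09-fold, Plvap, of the diaphragm of vessel pores, rose 4.82-fold, Mcam rose 3.66-fold and adrenomedullin, Adm, fell 4.76-fold. Tcf15 fell 3.32-fold, Cd36 fell 2.33-fold, the lipase anchor Gpihbp1 fell 2.21-fold, the factor Meox2 fell 2.21-fold and Cyp26b1 fell 29.4-fold.

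Birc5, Ccna2, Mki67 and Aurkb had no count at day 0 and were at least 118-fold, at least 55.9-fold, at least 46.1-fold and at least 25.2-fold higher. Complement C1qa, C1qb and C1qc, made by macrophages, rose 277-fold, 371-fold and 263-fold, and the macrophage gene Wfdc17 151-fold, at 0.109, 0.102, 0.108 and 0.113 of the top class. Il1b rose 94.7-fold, Ccl4 rose 55.5-fold and Ccl3 rose by a count ratio of 154 (95% counting interval 42.1 to 1281), at 0.181, 0.0805 and 0.104 of the top class. Postn rose 36.8-fold, Timp1 rose 28.7-fold, Tnc rose 24.8-fold and Adam12 rose by a count ratio of 63.8 (95% counting interval 10.8 to 2584), at 0.0272, 0.0291, 0.0196 and 0.0608 of the top class. The globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, pairs of near copies of red cell origin, fell 64.1-fold, 27.6-fold, 27.7-fold and 33.0-fold, from a day 0 spread as large as the mean (78.0 ± 102 against 5047 ± 5619 CPM for Hba-a1).

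Of the interferon-induced genes, 10 of 15 rose and 5 did not pass (12 rose adjusted over the list alone, camera adjusted p = 7.39e-11, 0.105 estimated). Among adhesion genes, 3 of 5 rose and 2 did not pass (3 rose adjusted over the list alone, camera adjusted p = 0.0312, 0.308 estimated). Of the tip cell genes, 4 of 15 rose, 5 fell and 6 did not pass (5 rose and 5 fell adjusted over the list alone, camera adjusted p = 0.852). Among capillary genes, 5 of 12 fell and 7 did not pass (7 fell adjusted over the list alone, camera adjusted p = 0.000285, 0.308 estimated). Of the cell-cycle genes, 15 of 24 rose and 9 did not pass (17 rose adjusted over the list alone, camera adjusted p = 5.09e-11, 0.308 estimated). Among cytokines, 6 of 10 rose and 4 did not pass (6 rose adjusted over the list alone, camera adjusted p = 1.15e-07, 0.105 estimated). Of the fibrillar matrix genes, 12 of 21 rose and 9 did not pass (15 rose adjusted over the list alone, camera adjusted p = 5.05e-10, 0.166 estimated). Transcripts of other cells moved beside these. Among macrophage markers, 7 of 7 rose (7 rose adjusted over the list alone, camera adjusted p = 4.98e-14, 0.105 estimated). Of the erythroid markers, 5 of 5 fell (5 fell adjusted over the list alone, camera adjusted p = 0.00152, 0.308 estimated). Among mature fibre transcripts, 11 of 11 fell (11 fell adjusted over the list alone, camera adjusted p = 1.06e-14, 0.105 estimated). Cells led by mural markers were 16.0% ± 1.59 of endothelial cells at day 5 and 9.89% ± 2.61 at day 2, against 2.84% ± 2.10 at day 0. Of 11234 genes, edgeR called 1706, 1047 up and 659 down, and 36 of 36 named changed genes had the libraries of the days apart. Simulation recovered 70% of 4-fold and 12% of 2-fold changes. The count was 696, 1007 and 788 without day 5 A, B and C, 2706 without day 0 C, 353 without the libraries at odds with their sex labels, and 1081 with only cells led by endothelial markers.

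**Figure D4:**
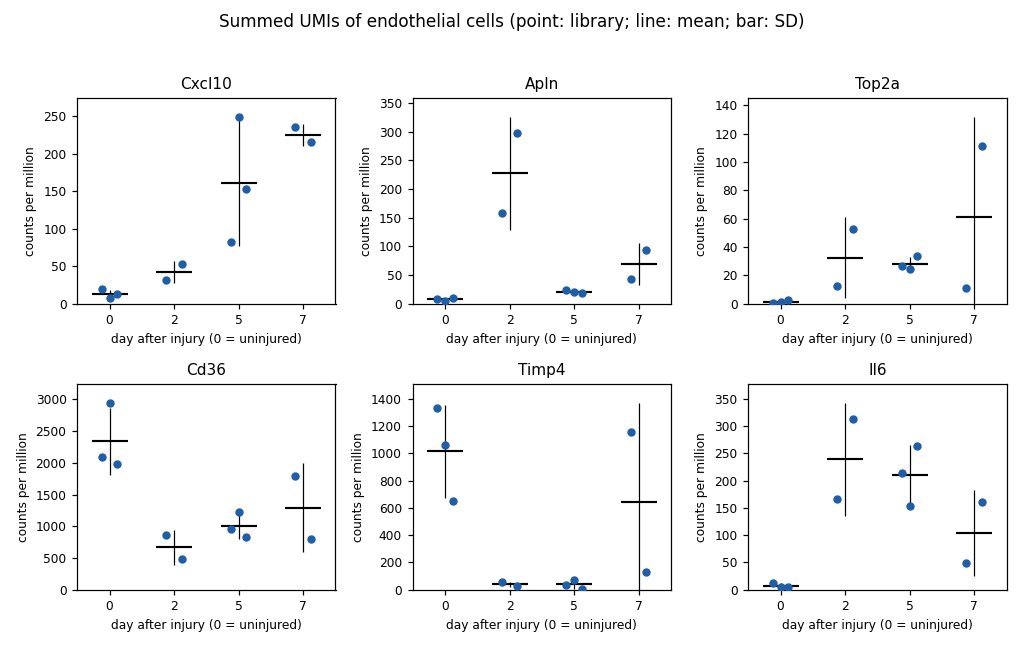
Level of Cxcl10, Apln, Top2a, Cd36, Timp4 and Il6 (CPM, y axis) in endothelial cells of each library by day after notexin (x axis), with the mean ± SD and error bars stopped at 0. Il6 rises from 7.50 ± 4.85 at day 0 to 210.1 ± 54.9 at day 5.

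Endothelial cells 7 days after injury, against uninjured ones, carried more of some interferon-induced and chemokine transcripts. Cxcl10 rose 16.9-fold, from 13.2 ± 5.55 to 225 ± 14.3 CPM (SD, n = 3 and 2; log2 change 4.08 ± 0.47, edgeR adjusted p = 0.00719). Ifit1 rose 6.57-fold, Irf7 5.30-fold and the ubiquitin-like modifier Isg15 4.22-fold. Il6 rose 13.5-fold, Ccl2, which draws monocytes, 12.7-fold, Ccl7 9.35-fold, Apln 8.76-fold and the matrix protease Adamts4 11.9-fold. Of the division genes, Top2a rose 47.0-fold (to 10.7 and 111 CPM) and Cenpf 38.4-fold. Birc5 (75.3 ± 83.7 CPM) and Ccna2, with no count at day 0, were at least 230.1-fold and 104-fold higher. Klra9, uncertain as a near copy, fell 10.3-fold, and Cap1, which turns over actin, 4.05-fold.

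Of the interferon-induced genes, 5 of 15 rose and 10 did not pass (13 rose adjusted over the list alone, camera adjusted p = 3.38e-26, 0.0215 estimated). Among cytokines, 3 of 10 rose and 7 did not pass (4 rose adjusted over the list alone, camera adjusted p = 3.05e-12, 0.0215 estimated). Of the cell-cycle genes, 5 of 24 rose and 19 did not pass (23 rose adjusted over the list alone, camera adjusted p = 6.71e-32, 0.180 estimated). Among adhesion genes, 5 of 5 did not pass (3 rose adjusted over the list alone, camera adjusted p = 0.000686, 0.218 estimated). Of the macrophage markers, 7 of 7 did not pass (5 rose adjusted over the list alone, camera adjusted p = 1.47e-06, 0.238 estimated). Of 11234 genes, edgeR called 37, 29 up and 8 down, with 1475 at unadjusted p under 0.05, and 15 of 15 named changed genes had the libraries of the days apart. Simulations found 65% of 4-fold and 4% of 2-fold changes. The count was 8, 9 and 129 without day 0 A, B and C, 70 with only cells led by endothelial markers and 358 with DESeq2. Without day 7 C, without day 7 D, or without the libraries at odds with their sex labels, day 7 has only D or only C. No count is read there.

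Macrophage-class cells of day 5 were set against those of day 2, since uninjured muscle holds few of them. The class joins different annotated types on the 2 days. Some genes of the inflammatory list fell and some of the repair list rose. Arginase 1, Arg1, in the inflammatory list but also a marker of alternative activation, fell 24.9-fold, from 138 ± 127 to 5.53 ± 1.62 CPM (SD, n = 2 and 3; log2 change -4.64 ± 0.64, edgeR adjusted p = 0.00997). Versican, Vcan, fell 13.8-fold, thrombospondin, Thbs1, fell 7.46-fold, the secreted Dmkn fell 14.9-fold, Ifitm1 fell 8.79-fold and Igfbp6 fell 6.67-fold. Pltp, which moves phospholipid onto lipoproteins, rose 13.6-fold, from 40.0 ± 12.7 to 544 ± 93.2 CPM (edgeR adjusted p = 0.000384). C1qa rose 5.90-fold, C1qc rose 5.07-fold and the fractalkine receptor Cx3cr1 rose 5.26-fold. Lag3, a ligand of class II molecules, rose 9.88-fold, Cd72, an inhibitory receptor, rose 9.33-fold, the ion pump subunit Fxyd2 rose 9.13-fold and the elastase Mmp12 rose 8.75-fold. H2-Eb1, a class II chain, rose 3.01-fold, and its activator Ciita rose 3.26-fold. Some enzymes of cholesterol synthesis fell, Sqle 3.36-fold, Fdps 3.07-fold and Idi1 2.47-fold. Cxcl5, Cxcl1 and Il6 fell 213-fold, 7.30-fold and 6.47-fold, at 0.107, 0.0674 and 0.0432 of the top class.

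Among inflammatory macrophage genes, 6 of 13 fell and 7 did not pass (8 fell adjusted over the list alone, camera adjusted p = 4.38e-06, 0.423 estimated). Of the repair macrophage genes, 5 of 18 rose and 13 did not pass (7 rose adjusted over the list alone, camera adjusted p = 0.00319, 0.470 estimated). Among antigen-presentation genes, 2 of 7 rose and 5 did not pass (7 rose adjusted over the list alone, camera adjusted p = 0.00301, 0.470 estimated). Of the cytokines, 3 of 12 fell and 9 did not pass (6 fell adjusted over the list alone, camera adjusted p = 0.00420, 0.493 estimated). Among genes of cholesterol synthesis, 5 of 15 fell and 10 did not pass (8 fell adjusted over the list alone, camera adjusted p = 0.000349, 0.575 estimated). For genes of the cell cycle, 24 of 24 did not pass (0 passed adjusted over the list alone, camera adjusted p = 0.293). Transcripts of other cells moved beside these. Among embryonic sarcomere genes, 6 of 9 rose and 3 did not pass (6 rose adjusted over the list alone, camera adjusted p = 5.80e-23, 0.0573 estimated). For neutrophil markers, 5 of 5 did not pass (1 fell adjusted over the list alone, camera adjusted p = 0.124). For platelet markers, 1 of 3 fell and 2 did not pass (2 fell adjusted over the list alone, camera adjusted p = 0.0329, 0.423 estimated). Of 13139 genes, edgeR called 984, 603 up and 381 down, and 24 of 24 changed genes that the naming rule picks had the libraries of the days apart. Simulated 4-fold changes were recovered at 81% and 2-fold at 33%, and 12.3% of calls were unchanged genes. The count was 122 without day 2 D, 171, 157 and 387 without day 5 A, B and C, 38 without the libraries at odds with their sex labels, 206 with the labelled sex as a term and 2540 with DESeq2.

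Macrophage-class cells 7 days after injury were set against those of day 5, whose monocyte annotation is lacking at day 7. The resident annotation held 115 of 201 cells in day 7 C and 189 of 895 in D, a mix not taken out. Mgl2, a lectin of resident macrophages, rose 48.7-fold, from 8.37 ± 1.31 to 412 ± 507 CPM (SD, n = 3 and 2; log2 change 5.61 ± 0.96, edgeR adjusted p = 0.0288). The resident lectin Cd209d rose 43.2-fold, the ribonuclease Ear2 rose 19.3-fold, the growth factor receptor Fgfr1 rose 10.7-fold, the tubulin-binding Tppp3 rose 8.97-fold and Il6 rose 13.0-fold. The last 3 stood at 0.345, 0.347 and 0.105 of the top class. The lysosomal proteases Ctsk and Ctsl fell 4.84-fold and 3.94-fold, the scavenger receptor Msr1 2.82-fold, the creatine carrier Slc6a8 3.1-fold, Gde1 2.99-fold and cyclin Ccnb1 3.87-fold.

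Of the antigen-presentation genes, 7 of 7 did not pass (7 rose adjusted over the list alone, camera adjusted p = 7.18e-05, 0.216 estimated). Among cell-cycle genes, 1 of 24 fell and 23 did not pass (2 fell adjusted over the list alone, camera adjusted p = 0.00267, 0.571 estimated). Of the inflammatory macrophage genes, 13 of 13 did not pass (0 passed adjusted over the list alone, camera adjusted p = 0.828, with a median log2 change of 0.44, a mean of -0.16 and a test directed down). Among repair macrophage genes, 18 of 18 did not pass (0 passed adjusted over the list alone, camera adjusted p = 0.0328, 0.398 estimated). Markers of other cells moved beside these. Of the resting FAP genes, 5 of 13 rose and 8 did not pass (10 rose adjusted over the list alone, camera adjusted p = 2.11e-07, 0.137 estimated). Among capillary genes, 4 of 12 rose and 8 did not pass (8 rose adjusted over the list alone, camera adjusted p = 2.11e-07, 0.216 estimated). Median log2 changes were 6.25 for erythroid, 2.72 for endothelial and 1.61 for FAP markers, 1.75 for fibre transcripts and 0.93 for early genes of digestion. Of these, 0 of 4, 2 of 5, 1 of 5, 0 of 11 and 2 of 16 rose and 0 fell (0, 3, 3, 8 and 10 rose adjusted over the list alone). Of 13139 genes, edgeR called 289, 253 up and 36 down, or 87.5% up against 68.7% in DESeq2. Simulation recovered 69% of 4-fold and 12% of 2-fold changes, and 14.7% of its calls were unchanged genes. The count was 2, 3 and 19 without day 5 A, B and C and 111 without genes under 10% of another class's level. DESeq2 called 1160.

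**Figure D5:**
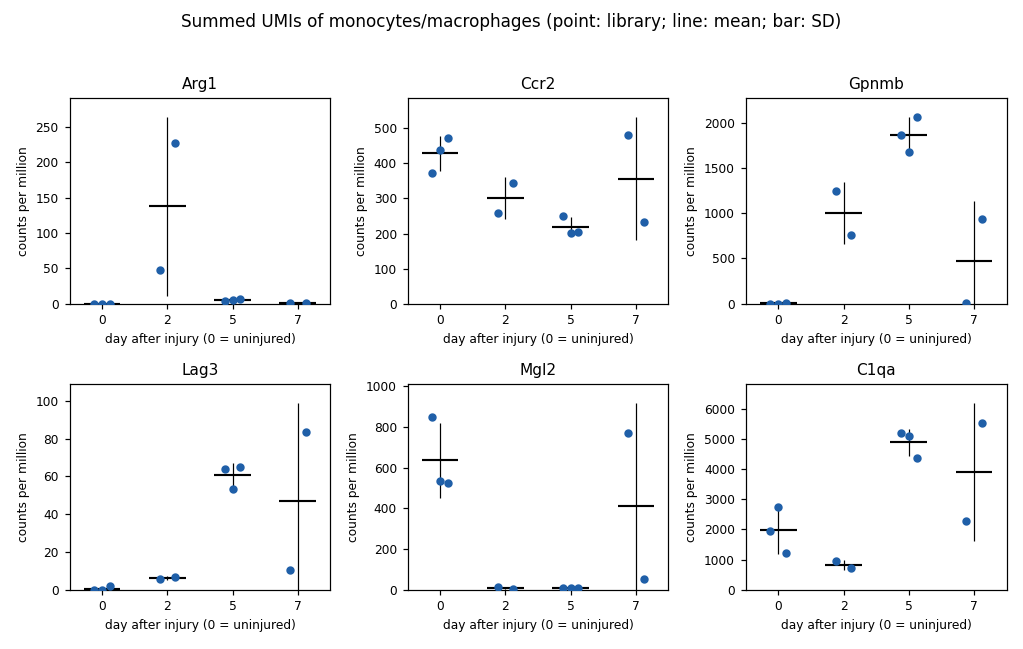
Level of Arg1, Ccr2, Gpnmb, Lag3, Mgl2 and C1qa (CPM, y axis) in macrophage-class cells of each library by day after notexin (x axis), with the mean ± SD and error bars stopped at 0. Arg1 falls from 137.8 ± 127 at day 2 to 5.53 ± 1.62 at day 5.

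Over the 10 comparisons and 28 lists, camera with its preset correlation made 162 calls, 6 of which held with an estimated correlation. These were embryonic sarcomere in day 7 MuSCs, cell cycle in day 2 FAPs, cytokines in day 2 and day 7 endothelial cells, inflammatory macrophage genes in day 2 and interferon-induced genes in day 7 endothelial cells. The test fry, which asks whether a list's genes move on balance one way, made 98. In the simulated data, unchanged genes were 2.33% to 8.33% of calls in the other 7 comparisons, so the share of false calls can exceed the threshold of 5%. Beyond the lists given with each comparison, early genes of digestion fell for 11 of 16 in day 5 FAPs and 5 of 16 in day 2 and day 5 endothelial cells (11, 7 and 6 adjusted over the list alone, with 1 rise in the last). Fibre transcripts passed for 0 of 11 in day 7 MuSCs, FAPs and endothelial cells (7, 9 and 3 fell adjusted over the list alone).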

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

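The tests of myogenic transcripts at day 2 and of doublets among mural-led cells and the counts of endothelial UMIs in mural-led cells were chosen only after the result was seen; the interaction was not in the plan but was written before its result was seen, as were the other tests in this part.

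Endothelial cells and FAPs changed differently after injury in a fit with a term per library and an interaction term: 1260 of 13104 genes at day 2, 725 of them with the endothelial change higher and 535 with the FAP change higher, 1914 at day 5 (1128 and 786) and 15 at day 7, all 15 with the endothelial change higher. These are differences between groups in the same contrast, by edgeR at an adjusted p of 0.05. Macrophage transcripts stood at 10.9% and 11.4% of the macrophage level in day 2 endothelial cells and 2.75% and 3.72% in FAPs, and at 15.6%, 7.66% and 5.97% in day 5 endothelial cells and 5.36%, 5.49% and 3.01% in FAPs. Neither these nor the mural-led cells, 16.0% of day 5 endothelial cells, were taken out of these counts.

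Sex transcripts stand in libraries where the label has none, a signal the comparisons do not use, in libraries that they do. Day 5 B, labelled female, held 109 CPM of Y-linked genes, and day 5 C and day 7 D, labelled male, held 779.8 and 936 CPM of Xist. Day 5 A, labelled male, held 0.118 CPM of Xist. A swap of the labels of day 5 B and C would put these libraries right, day 7 D would need a partner outside day 7 C, and no test here tells a wrong sex label from a wrong library. Xist ran from 443 to 936 CPM in every library of days 0, 2 and 7, so by transcripts sex stays open, untested, as a biological difference in comparisons with day 5.

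Macrophage transcripts in FAPs and endothelial cells at day 5 form a first pattern. In FAPs, the 5% of cells with the most macrophage UMIs held 56.7% ± 9.94 of them (SD, 3 libraries), within its spread of 50%, so free RNA and macrophages or doublets cannot be told apart. In endothelial cells they held 66.6% ± 12.8, more than free RNA alone allows, and macrophages or doublets among these cells may account for most. Yet 97.1% to 100% of endothelial cells and 99.5% to 100% of FAPs held at least 1 such UMI, at medians of 5.79 to 12.3 per 10000 against 383 to 418 in macrophages, so macrophages or doublets alone do not cover the endothelial pattern either. No biological source was tested.

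Myogenic transcripts in day 2 cells annotated as antigen-presenting form the second. Of 560 such cells, 24 (4.29%) held at least 3 myogenic UMIs, 19 in C and 5 in D. Their median depth of 21138.5 UMIs against 8611 in those without myogenic UMIs goes the way of doublets, which stay open for other partners. Doublets with a macrophage would carry a high macrophage content, but the median content was 6.15% of that of the other cells (quartiles 5.03 and 10.0). Free RNA would reach cells of other annotations, and 0 of 4964 had them, counted without a test. The myogenic UMIs of the 24, at a median of 7.82 per 10000 against 10.6 in day 5 MuSCs, may be those of myogenic cells named with another type, a hypothesis found and tested on the same cells.

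Mural transcripts in day 5 endothelial cells form the third. Cells led by mural markers were 16.0% ± 1.59 of them, or 0.826 ± 0.082 of the mean among endothelial and smooth muscle cells of days 0 and 7 (19.4%, range 13.0 to 30.0). They were 2.84% and 1.87% of endothelial cells alone on those days. Mural cells counted as endothelial where no smooth muscle was annotated are thus a candidate explanation. They held a median of 23.9 ± 3.48 endothelial UMIs per 10000, against 14.6 to 26.5 in annotated smooth muscle cells led alike. Doublets would need a higher depth, and the UMI ratio was 1.21 ± 0.034. All endothelial cells not so led held 37.1 ± 1.09 endothelial UMIs. Those of them with at least 10 mural UMIs held 38.3 ± 2.13, so mixing stays open for these as well.

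The 6 libraries of days 0 and 5 split in 10 ways with the real one, too few for a share under 0.05. The real grouping gave 2588 genes in MuSCs, 4404 in FAPs and 1706 in endothelial cells (1 of 10 gave as many in each), and the highest other gave 0 in edgeR, with at most 184, 704 and 1118 genes at unadjusted p under 0.05 in the other groupings. No other tool was run on these.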

How the results depend on the processing

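The settings with cells led by their own markers, without genes under 10% of another class's level, without libraries whose sex transcripts go against their labels, and with a common depth floor were chosen only after the results were seen. The other settings, the gene lists and the comparisons of this part were fixed before the data were examined. MuSCs of day 2 were not run under any setting, for lack of annotated cells. Where 1 library of day 2 or 7 was left out, the lone one left was assumed to vary like the other days. The cause was not tested for any difference given here, except where a setting's own construction shows it.

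Class shares differed between days for 9 of 9 classes, 6 of them void against days without their annotation, and for 7 to 9 with each library left out, 7 of 7 among nonhematopoietic cells (with FAPs then higher at day 2, 65.0% against 36.3%, not lower, and endothelial cells at 35.0% against 38.3%), and all 9 on the log2 scale, with edgeR, with edgeR and the replicate letter, and with the depth floor. Of 9 MuSC genes, 3 differed in the share of cells with a UMI, 1 after thinning to 2000 UMIs and 4 without thinning, both without Pax7. With 1 library left out 0 to 3 did (3 to 5 at unadjusted p under 0.05), by exact tests that 1 gene alone cannot pass.

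Counts of changed genes with each library of the 2 days compared left out (those of the other days, also in the fit, were not) ran from 1149 to 2160 for MuSCs at day 5 and 5 to 1483 at day 7, 1969 to 4991, 2511 to 4855 and 2 to 560 for FAPs at days 2, 5 and 7, 361 to 2717, 696 to 2706 and 7 to 507 for endothelial cells, and 122 to 672 and 2 to 909 for macrophages at day 5 against 2 and day 7 against 5. Those that moved a count by over 1.5 times follow. MuSCs at day 5 gave 1149 without day 0 C and 1256, 1329 and 1199 without day 5 A, B and C, and at day 7 gave 11, 5, 1483 and 11 without day 0 A, day 0 B, day 7 C and day 7 D. FAPs gave 2344 and 1969 without day 2 C and D, 2550 and 2511 without day 5 A and C, and at day 7 gave 25, 560 and 2 without day 0 C, day 7 C and day 7 D. Endothelial cells gave 592 and 361 without day 2 C and D, and at day 5 gave 2706, 696, 1007 and 788 without day 0 C and day 5 A, B and C. At day 7 they gave 8, 9, 129, 507 and 7 without day 0 A, B and C and day 7 C and D. Macrophages at day 5 against 2 gave 122 without day 2 D and 171, 157 and 387 without day 5 A, B and C. At day 7 against 5 they gave 2, 3 and 19 without day 5 A, B and C and 79 and 909 without day 7 C and D.

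DESeq2 gave 704 genes (331 up, 373 down) for MuSCs at day 7, 253 (181 and 72) for FAPs and 358 for endothelial cells at day 7, and 2540 and 1160 (797 and 363) for macrophages at day 5 against 2 and day 7 against 5, against 24, 6, 37, 984 and 289. Without a filter MuSCs, FAPs and endothelial cells at day 7 gave 318, 11 and 130. With at least 50 cells MuSCs at day 7 gave 5 and macrophages 2239 and 184. This setting leaves fewer libraries, and equals the result in the text where no library drops out. With only the libraries of the days compared, counts were 7 for MuSCs at day 7, 2881 and 2 for FAPs at days 2 and 7, 966 and 0 for endothelial cells at days 2 and 7, and 4240 and 41 for macrophages. The count of 0 is by edgeR, with 707 genes at unadjusted p under 0.05.

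With the labelled sex as a term, which the transcripts go against in 3 libraries, counts were 836 and 9 for MuSCs, 1402 and 3 for FAPs at days 5 and 7, 340 and 8 for endothelial cells at days 5 and 7, and 206 for macrophages at day 5 against 2. Without those 3 libraries they were 423 and 10 for MuSCs, 2922, 1143 and 1 for FAPs, 979, 353 and 0 for endothelial cells, and 38 and 80 for macrophages. The count of 0 is by edgeR, with 344 genes at unadjusted p under 0.05. With the replicate letter as a block, counts were 105 for MuSCs at day 7, 1932 for FAPs at day 2, 374 and 1 for endothelial cells at days 2 and 7, and 163 for macrophages at day 5 against 2. No pairing by letter was seen: correlations across genes, which are not independent, between days 0 and 5 within a letter were at most 0.0886 in size. With cells led by their own markers, not run for MuSCs, counts were 1081 and 70 for endothelial cells at days 5 and 7 and 117 for macrophages at day 7 against 5, and without genes under 10% of another class's level 111 for the last.

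The list calls by camera were 162, with an estimated correlation 6, and by fry 98. For 230 named genes, 2777 of 3463 values under the settings kept their direction and side of the threshold, 670 kept the direction and lost the call, 11 gained it, 5 moved and 0 turned round. Of all 984 called genes in macrophages at day 5 against 2, 4 turned round with cells led by their own markers: Prrx2, Cald1, Prkcdbp and Sdc2 fell and rose there. Calls lost were 76 without the libraries at odds with their sex labels, 65 with the labelled sex, 61 with the replicate letter and 1 with relative log scaling.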

Other observations

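None of the tests in this part was chosen only after the result was seen, but only those of macrophages against day 0 were in the plan, the others were added once the files were at hand, and the genes named here were picked after their values were seen.

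MuSCs of day 7 against day 5 differed in 343 genes, 207 up and 136 down. Of the quiescence genes, 3 of 12 rose and 9 did not pass (7 rose adjusted over the list alone, camera adjusted p = 0.000364, 0.272 with an estimated correlation), with Chrdl2 from 0.591 ± 0.334 to 126 ± 163 CPM over 2 unlike libraries (edgeR adjusted p = 0.0193). Transcripts of other cells and of digestion moved too. Of the macrophage markers, 3 of 7 fell and 4 did not pass (7 fell adjusted over the list alone, camera adjusted p = 4.71e-09, 0.150 estimated). For fibre transcripts, 8 of 11 rose and 3 did not pass (10 rose and 1 fell adjusted over the list alone, camera adjusted p = 1.46e-09, 0.153 estimated). For early genes of digestion, 9 of 16 rose and 7 did not pass (15 rose adjusted over the list alone, camera adjusted p = 5.87e-11, 0.245 estimated).

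FAPs of day 5 against day 2 differed in 441 genes (246 up, 195 down). FAPs of day 7 against day 5 differed in 869 (421 up, 448 down). Gsn rose from 1655 ± 864 to 26029.7 ± 29718 CPM over 2 unlike libraries (edgeR adjusted p = 0.0194) and Pi16 from 135 ± 85.0 to 1564 ± 222 CPM, and Ccnb1 (36.4-fold), Birc5 (33.6-fold) and Cenpa (29.1-fold) fell. Beside these, of the macrophage markers, 3 of 7 fell and 4 did not pass (7 fell adjusted over the list alone, camera adjusted p = 5.03e-07, 0.202 estimated). For fibre transcripts, 9 of 11 rose and 2 did not pass (11 rose adjusted over the list alone, camera adjusted p = 1.01e-13, 0.202 estimated). For early genes of digestion, 7 of 16 rose and 9 did not pass (12 rose adjusted over the list alone, camera adjusted p = 3.45e-10, 0.202 estimated).

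Endothelial cells of day 5 against day 2 differed in 4 genes by edgeR, with 1042 at unadjusted p under 0.05. Day 7 against day 5 gave 62 (3 up, 59 down), with the mural genes Notch3 (7.73-fold), Kcnj8 (6.60-fold) and Higd1b (9.39-fold) lower. Mural-led cells were 16.0% of endothelial cells at day 5, when no smooth muscle was annotated, and 1.87% at day 7, when it was. Of the macrophage markers, 7 of 7 did not pass (7 fell adjusted over the list alone, camera adjusted p = 1.02e-15, 0.176 estimated). Macrophages of day 0 carry the resident annotation alone (164 cells), so their comparisons with day 2 (2374 genes), day 5 (2238) and day 7 (2) set different annotated types side by side.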
